A study of Mus musculus and Macaca fascicularis with 80 samples.

How the data were processed

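RNA was measured in 80 libraries of sorted nuclei, 74 from mouse and 6 from monkey. Per the labels' protocols, nuclei were isolated from snap-frozen visual cortex, stained with antibodies and Dapi, and sorted into lysis buffer. Complementary DNA was made by a method based on Smart-Seq2, with ERCC spikes, and Nextera XT libraries were amplified over 17 cycles. The mice were C57BL/6, and the genotype was Vip-Cre in the 6 virus libraries, Ndnf-Cre::INTACT in the 6 libraries of the NDNF sort and Vip-Cre::INTACT in the other mouse libraries, per the labels. Monkey libraries carried the tissue "cortex", a mouse genotype and a mouse genome build in their labels, and the build used for their alignment was not given in the sources used here. The deposited values were gene counts, whole numbers per gene and library, in a table for mouse and a table for monkey. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with STAR 2.5.3a to mm10. The version of cutadapt, the counting tool and the strand used in counting were not given in the sources used here.

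The mouse table held 55335 genes, of which 55154 were given a symbol, and the remainder took up 0.0252% of the counts. The monkey table held 37818 genes, of which 16781 were joined by their Ensembl identifier. Each count column of the series tables was compared with the count file of its sample: 78 of 80 were identical, and the files of VIP and nonVIP replicate 1 at time 0.5 were exchanged relative to the table. The series table was used because its columns carry the sample titles. This choice was made after the Vip counts of those libraries had been seen, and the effect of the other choice is given in the closing section.

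Each comparison was fitted on gene counts with edgeR 4.0.16 in R 4.3.3. Low counts were filtered by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and quasi-likelihood F tests were two-sided. Values of p were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. SE was the log2 fold change over the square root of F. CPM values were computed from the counts over scaled library sizes, times 1e+06, and SD is between libraries of a group. Where a group had no counts, the fold is a lower bound with a floor of 3 counts over that group. This bound covers counting alone and not the spread between libraries, so the true fold may be smaller. VIP and nonVIP libraries of each number of nuclei, of the biological replicates and of the virus sort were fitted by themselves, as were NDNF and nonNDNF, monkey and mouse Prox1 sorts. All 24 time-course libraries were fitted together, and interactions compared the difference in one pair of groups with that in another. The virus and NDNF interactions took the 100-nuclei biological replicates as the transgenic VIP sort.

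Before the data were examined, 18 lists with 271 entries were fixed: VIP subclass, caudal ganglionic eminence interneurons, NDNF and Lamp5 subclass, Sst subclass, Pvalb subclass, pan-GABAergic, excitatory neurons, pan-neuronal, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, vascular cells, immediate early genes, late response genes, heat shock genes, interferon response and nuclear long non-coding RNAs. Lists were tested with camera in limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Values of p were adjusted over the lists of a comparison. Members were also counted after adjustment over the list alone. Also fixed before the data were examined were the comparisons, the tests, the alternatives and the rule for naming genes. The rule named Vip, Ndnf, Prox1, Rbfox3, Slc17a7 and Gad1, and the 4 members of each list with the smallest adjusted p. In each direction it also named the 5 called genes of largest log2 fold change. These needed at least 10 CPM in the higher group and no overlap between the libraries of the 2 groups. For interactions the last condition was left out. Predicted genes, clones, mitochondrial genes and spike-ins were not taken among these 5. The text names genes from this rule, except that all genes passing in the time-course interactions are named. Genes named for another reason are given as chosen after their values were seen.

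Genes detected had at least 1 count after each library of the nuclei series was thinned to 2504404 counts, the smallest total. Their relation to the log2 number of nuclei was tested by 1e+05 permutations, two-sided. Replicate correlations were computed on log2 of CPM plus 1. Sex of the mouse libraries was read from Xist against Y-linked genes. Mouse and monkey genes were matched by symbol. Log2 fold changes at different times were set against 20 simulations of unchanged groups that shared the time 0 libraries. Libraries were also split in every other way into groups of the same size. For interactions, drawn splits were used that numbered 30 with the real one.

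Precision differed between the fits. Median biological coefficients of variation ranged from 0.33 to 0.771 over the fits, and the mitochondrial share from 0.0513% to 0.968% in mouse. The fits were tested on simulated data in which 200 genes were changed. For 100 nuclei edgeR recovered 10.4%, 40.3% and 65.2% of genes changed 2-fold, 4-fold and 8-fold, with 6 unchanged genes called. For the biological replicates the shares were 0%, 16.4% and 43.9%, for the virus sort 0%, 22.4% and 43.9% and for monkey Prox1+ against Prox1- 7.46%, 49.3% and 60.6%. For VIP nuclei at time 0.5 they were 0%, 8.96% and 24.2%, and for the interaction at that time 0%, 2.99% and 9.09%. A gene without a call in the time course was therefore often beyond the reach of the fit. DESeq2 1.42.0 called 33, 55, 64, 14, 21 and 27 unchanged genes in these 6 simulations.

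Alternatives fixed before the data were examined were DESeq2 Wald tests, relative log expression scaling, no low-count filter, a block for replicate number, leaving out each library in turn, a joint fit of the 30 libraries of the nuclei series, counts thinned to equal totals, technical replicates summed as an additional biological replicate, and fits of part of the time course. Chosen after seeing the data were fits without genes on chromosomes X and Y, sex by transcripts as a covariate, the per-sample count files in place of the series table, detection without the 50 nuclei libraries, and leaving out each library in the species comparison. Gene coordinates were used only to find overlapping genes and genes on chromosomes X and Y. Some gene results are not reported here. Reads were not used here, the ERCC spikes were not analysed here, and sex was not analysed in monkey. Tables were read with data.table, version 1.17.8, and figures were drawn with matplotlib.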

Results

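The data comprised 80 RNA-seq libraries prepared from small numbers of sorted nuclei, 74 from mouse and 6 from cynomolgus monkey, in 29 groups. Per the labels, 30 mouse libraries held 50, 100, 200, 500 or 800 VIP or nonVIP nuclei with 3 technical replicates per group. Another 4 were biological replicates of 100 nuclei, 6 came from a virus-based VIP sort and 6 from an NDNF sort. A time course of VIP and nonVIP nuclei at times 0, 0.5, 1 and 3 gave 24 libraries, and the unit of time was not stated in the labels. Mouse Prox1+ NeuN+ and Dapi nuclei gave 4 libraries, and monkey Prox1+ NeuN+, Prox1- NeuN+ and Dapi nuclei gave 6, all titled technical replicates. Groups held 3 libraries except for the biological replicates and the Prox1 and Dapi sorts of either species, which held 2. Counts per library ranged from 2504404 to 15826713 in the series of nuclei numbers, from 4247775 to 11348454 in the biological replicates and from 11890297 to 14862359 in the virus sort. The NDNF sort held 4181946 to 10028786, mouse Prox1 and Dapi 7765030 to 10066452, the time course 1099822 to 8551387 and monkey 2379944 to 5715632. Genes detected ranged from 14028 to 23283 in mouse and from 18997 to 20954 in monkey.

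To find the transcripts that marked VIP interneurons at a low input, libraries of 100 VIP nuclei were compared with libraries of 100 nonVIP nuclei. The neuropeptide gene Vip reached 3032 CPM (counts scaled to library size; SD 395, n = 3) against 1.01 (SD 0.909, n = 3), a log2 fold change of 11.47 (SE 0.37, edgeR adjusted p = 5.1e-08). Tac2, which encodes a tachykinin precursor, and the serotonin receptor gene Htr3a had no counts in nonVIP nuclei and were at least 418-fold and at least 292-fold higher. The peptide genes Crh (log2 fold change 7.80, SE 0.43) and Penk (4.82, SE 0.24), the receptor genes Egfr (4.71, SE 0.17) and Erbb4 (3.58, SE 0.43) and the RNA-editing family gene Adarb2 (5.99, SE 0.29) were all higher in VIP nuclei. Prox1, a transcription factor of interneurons from the caudal ganglionic eminence, rose by 3.72 (SE 0.23, edgeR adjusted p = 4.1e-06), from 15.3 CPM (SD 2.83) to 201 (SD 21.3). Gad1, which encodes a GABA-synthesizing enzyme, rose by 3.96 (SE 0.57, edgeR adjusted p = 0.000843), from 51.7 CPM (SD 48.5) to 804 (SD 42.8). The vesicular glutamate transporter gene Slc17a7 fell by 4.63 (SE 0.46, edgeR adjusted p = 7.24e-05), to 2.77 CPM (SD 1.6) from 70 (SD 16.5). Ndnf was at 0 in VIP nuclei and 10.1 CPM (SD 2.32) in nonVIP nuclei, at least 109-fold lower, and the neuronal splicing regulator gene Rbfox3 fell by 1.42 (SE 0.22, edgeR adjusted p = 0.00135).

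Cell-type lists fixed before the data were examined summarized the same sort. Of the VIP subclass list 15 of 18 tested genes were higher and 1 was lower, and the counts were also 15 and 1 when adjusted over the list alone (camera adjusted p = 1.63e-10, and 0.0206 with an estimated correlation). The list of interneurons from the caudal ganglionic eminence had 11 of 12 genes higher (4.33e-11 by camera, 0.0206 with an estimated correlation), and the pan-GABAergic list 10 of 12 (1.06e-08 by camera, adjusted p = 0.162 with an estimated correlation) or 12 over the list alone. Excitatory neuron genes were lower for 15 of 19 tested, among them Sv2b and Nrgn, or 16 over the list alone (7.97e-12 by camera, 0.0292 with an estimated correlation). All 12 oligodendrocyte genes were lower (3.89e-08 by camera, adjusted p = 0.162 with an estimated correlation), Aspa by at least 505-fold. Astrocyte genes were lower for 3 of 11 (0.0119, and adjusted p = 0.186 with an estimated correlation) and microglia genes for 2 of 9 (0.00267, and adjusted p = 0.231 with an estimated correlation). Of the Pvalb subclass list 4 of 9 genes were higher (0.00392, and adjusted p = 0.162 with an estimated correlation), and of the heat shock list 2 of 7 (0.00503, and adjusted p = 0.156 with an estimated correlation). The Pvalb list holds Erbb4, which was higher in VIP nuclei and is also on the pan-GABAergic list. Immediate early genes split into 6 higher and 1 lower of 22 (0.0234, and adjusted p = 0.231 with an estimated correlation): Fosl2 rose by 2.24 (SE 0.21) and Nr4a3 by 2.02 (SE 0.20), whereas Arc fell by 2.77 (SE 0.25).

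Other lists moved in both directions or not at all between VIP and nonVIP nuclei at 100 nuclei. In the NDNF and Lamp5 subclass list 6 of 15 genes were higher, Kit among them (2.97, SE 0.20), and 4 lower, Lamp5 among them (decreased by 2.71, SE 0.34; camera adjusted p = 0.86 for the list). The Sst subclass list had 3 higher and 2 lower of 9 (0.996 by camera), the late response list 7 higher and 4 lower of 20 (0.439) and the pan-neuronal list 1 higher and 3 lower of 11 (0.652). Nuclear long non-coding RNAs had 4 higher and 3 lower of 10 (camera adjusted p = 0.996), with Meg3 up by 0.93 (SE 0.11). Oligodendrocyte precursor genes were lower for 2 of 5 (camera adjusted p = 0.0542), while 0 of 3 vascular genes (0.469) and 0 of 6 interferon response genes (0.996) passed. Outside the lists, Slc5a7 was at least 78.3-fold higher in VIP nuclei, and Scube1 and Exph5 were at least 628-fold and at least 521-fold lower. By edgeR 2764 of 15385 genes passed an adjusted p of 0.05, 1290 higher and 1474 lower. These replicates were technical, so each p measured the spread between these libraries and not between animals. By transcripts the VIP libraries of 100 to 800 nuclei were male and the nonVIP ones female, so population and sex were not separated at these inputs. Igf1 (7.44, SE 0.48), with Igf1os antisense to it, remained uncertain because the strand used in counting was not given in the sources used here.

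The same comparison at 800 nuclei asked whether a larger input kept these differences. Vip averaged 2809 CPM (SD 163, n = 3) in VIP and 9.32 (SD 8.27, n = 3) in nonVIP nuclei, a log2 fold change of 8.25 (SE 0.61, edgeR adjusted p = 1.3e-05). Crh (8.55, SE 0.58), Adarb2 (5.55, SE 0.62), Prox1 (4.14, SE 0.41), Gad1 (3.97, SE 0.25) and Erbb4 (3.76, SE 0.30) were higher. Slc17a7 fell by 8.19 (SE 0.81, edgeR adjusted p = 9.88e-05) and Rbfox3 by 1.52 (edgeR adjusted p = 0.00421). Kcnv1, a modulatory potassium channel subunit gene, and the cholecystokinin receptor gene Cckbr had no counts in VIP nuclei and were at least 502-fold and at least 298-fold lower. Of the VIP subclass list 12 of 15 genes were higher and 1 lower (camera adjusted p = 9.19e-12, and 0.0291 with an estimated correlation), and of the pan-GABAergic list 10 of 12 were higher (1.12e-12, and 0.0291 with an estimated correlation). The caudal ganglionic eminence list had 9 of 12 higher (camera adjusted p = 3.29e-11; adjusted p = 0.0794 with an estimated correlation). A decrease was called for excitatory genes in 17 of 19 (camera adjusted p = 8.33e-14, and 0.0266 with an estimated correlation) and oligodendrocyte genes for 10 of 12 (5.84e-10; adjusted p = 0.0794 with an estimated correlation). Immediate early genes were higher for 6 of 19 and lower for 1 (camera adjusted p = 0.404), with Fosl2 up by 3.18 (SE 0.46) and Nr4a3 by 2.06 (SE 0.31). By edgeR 1767 of 14097 genes passed, 826 higher and 941 lower, and Ndnf was not tested at this input.

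At 50, 200 and 500 nuclei the marker genes moved the same way. Vip differed by 9.89 (SE 0.76), 10.03 (SE 0.31) and 8.11 (SE 0.95), with edgeR adjusted p of 8.87e-05, 5.29e-07 and 0.000709. Prox1 was higher by 2.45 (SE 0.43), 3.65 (SE 0.30) and 3.46 (SE 0.26), and Gad1 by 2.88 (SE 0.24), 4.07 (SE 0.29) and 3.65 (SE 0.31). Slc17a7 decreased by 4.05 (SE 0.43), 6.55 (SE 0.47) and 6.68 (SE 0.87). Rbfox3 did not change at 50 nuclei (−0.14, SE 0.18, edgeR adjusted p = 0.792) but fell by 1.72 (SE 0.32) at 200 and 1.35 (SE 0.32) at 500 nuclei. Both populations were male by transcripts at 50 nuclei, while nonVIP libraries of 200 and 500 were female, so input was not separated from sex. VIP subclass genes were higher for 11 of 17 with 1 lower, 13 of 16 and 12 of 17, and caudal ganglionic eminence genes for 9 of 12, 8 of 12 and 8 of 12. Excitatory genes were lower for 16 of 19, 17 of 20 and 16 of 19, and oligodendrocyte genes for 11, 11 and 12 of 12. By edgeR 1437 of 16632 genes passed at 50 nuclei, 2916 of 16210 at 200 and 2816 of 16280 at 500.

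**Figure D1:**
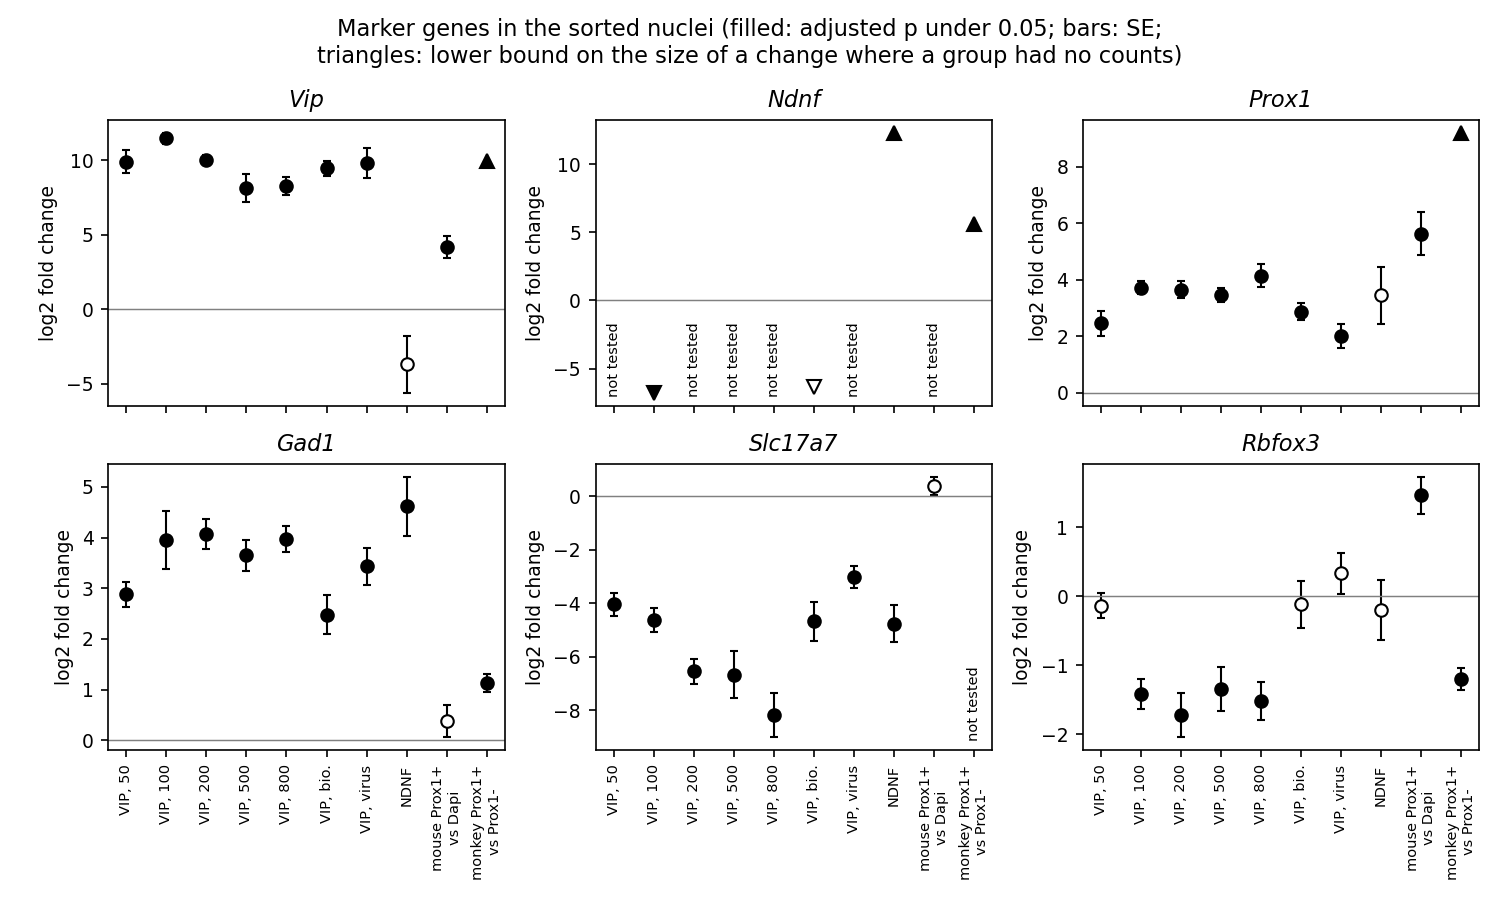
Vip, Ndnf, Prox1, Gad1, Slc17a7 and Rbfox3 in each sort. Points are log2 fold changes of the sorted population against its comparison population with bars of 1 SE, filled at an adjusted p below 0.05, triangles are lower bounds on the size of a change where a group had no counts, and the horizontal axis gives the comparison; Vip differed by 11.47 at 100 nuclei and Ndnf was at least 5050-fold higher in the NDNF sort.

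Genes shared across inputs gave a core of VIP and nonVIP transcripts. Of 13047 genes tested at all 5 numbers of nuclei, 283 were higher and 260 lower in VIP nuclei at every number, and 30 were called in both directions at different numbers. Of the genes called higher at 800 nuclei and tested in both, 40.5% were also called higher in the VIP libraries of 50 nuclei, and 72.7%, 77% and 78.1% in those of 100, 200 and 500. Of those called lower at 800 nuclei, 48.6%, 67.4%, 61.9% and 57.7% were also called lower at 50, 100, 200 and 500, so this share was highest at 100. The log2 fold changes of VIP against nonVIP nuclei at 800 correlated with those at 50, 100, 200 and 500 nuclei at r = 0.6, 0.695, 0.69 and 0.689. The nonVIP libraries were male by transcripts at 50 nuclei and female at 100 to 800. The inputs of 50 and of 100 or more therefore differed in sex as well. Replicates of VIP nuclei correlated at a mean r of 0.909, 0.911, 0.885, 0.868 and 0.886 from 50 to 800 nuclei, and those of nonVIP nuclei at 0.891, 0.925, 0.938, 0.94 and 0.918.

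The number of genes detected was then related to the number of nuclei after thinning each library to 2504404 counts. VIP nuclei yielded 17764 genes (SD 279, n = 3) at 50 nuclei, 17432 (SD 303) at 100, 15949 (SD 721) at 200, 15331 (SD 178) at 500 and 15615 (SD 203) at 800. Detection in VIP libraries fell with the logarithm of the number of nuclei (r = −0.887, permutation p = 1e-04, BH-adjusted 2e-04; rho = −0.775, p = 0.00107, BH-adjusted 0.00214). Without the 2 extreme libraries the value in VIP nuclei was −0.884 (permutation p = 0.00017). In nonVIP nuclei the count went from 18884 (SD 245) at 50 nuclei through 20491 (SD 134) at 200 to 19095 (SD 373) at 800, without a monotonic relation (r = 0.09, permutation p = 0.744; rho = 0.044, p = 0.892). Without its 2 extreme libraries the nonVIP value was 0.472 (permutation p = 0.105). It was −0.69 without the 50 nuclei libraries (permutation p = 0.0115), a choice made after seeing the data, and 0.652 without those of 800 (permutation p = 0.0227). By transcripts nonVIP libraries of 50 nuclei were male and those of 100 to 800 female, so sex changed with input there. In all 4 relations were computed, with two-sided tests over technical replicates.

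**Figure D2:**
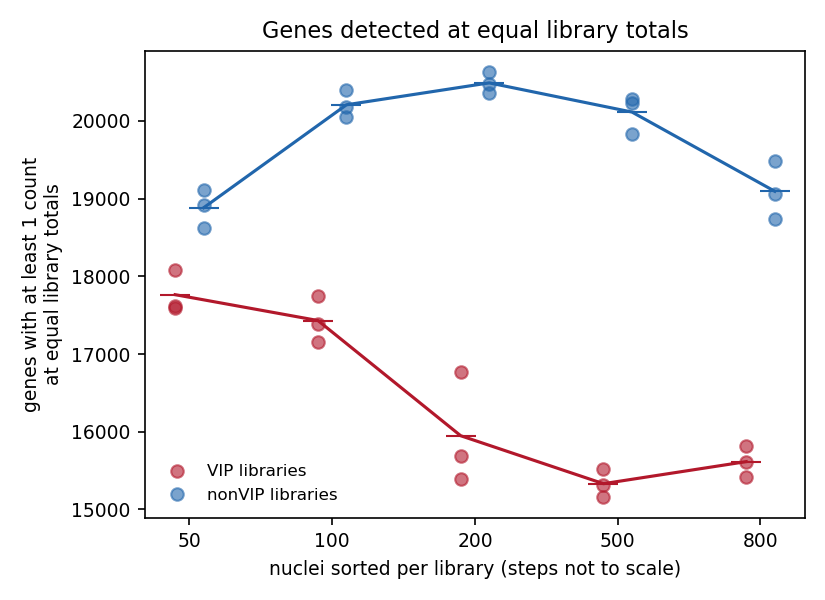
Genes detected at equal library totals against the number of nuclei. Points are libraries thinned to 2504404 counts and lines join group means, the horizontal axis gives the number of nuclei with steps not to scale and the vertical axis the genes with at least 1 count; VIP libraries went from 17764 genes at 50 nuclei to 15615 at 800.

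Sex-linked transcripts separated the VIP and nonVIP libraries of 100 to 800 nuclei. Xist, the transcript of the inactive X chromosome, was at 0.284 CPM (SD 0.0411) in VIP and 1962 (SD 217) in nonVIP nuclei at 100 nuclei, and fell by 12.69 (SE 0.23, edgeR adjusted p = 5.14e-10). The Y-linked genes Eif2s3y, Uty, Kdm5d and Ddx3y had no counts in those nonVIP libraries and were at least 438-fold, 323-fold, 214-fold and 184-fold higher in VIP nuclei. Over the VIP libraries of 100 to 800 nuclei the Y-linked sum ranged from 355 to 971 CPM, against 0 to 0.295 in nonVIP libraries, while Xist ranged from 0 to 2.04 and from 1730 to 2910. Sex by transcripts therefore went with population in these comparisons, and their calls do not separate them. At 50 nuclei both VIP and nonVIP libraries were male by transcripts, as were the biological replicates and the mouse Prox1+ and Dapi libraries. Virus and NDNF sorts were female in both populations. In the time course all libraries at time 0 were female and all at times 1 and 3 male, whereas at time 0.5 replicate 1 of each population was male and replicates 2 and 3 female. Xist and its antisense Tsix overlap, so their separate levels remained uncertain.

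**Figure D3:**
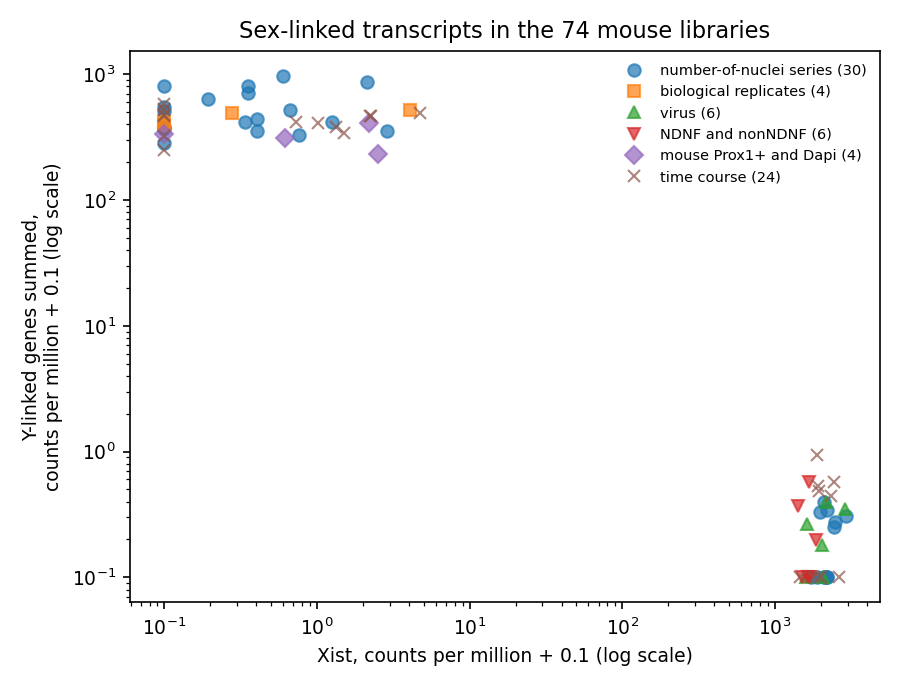
Sex-linked transcripts in the 74 mouse libraries. Points are libraries by experiment, with Xist in CPM on the horizontal and the sum of Y-linked genes in CPM on the vertical axis, both logarithmic after adding 0.1; nonVIP libraries of 100 to 800 nuclei held 1730 to 2910 CPM of Xist and VIP libraries 0 to 2.04.

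Biological replicates of 100 nuclei tested whether the VIP profile held between separate preparations. Vip reached 3941 CPM (SD 245, n = 2) against 5.4 (SD 2.75, n = 2), a log2 fold change of 9.44 (SE 0.48, edgeR adjusted p = 0.00301). Tac2 was at least 972-fold higher, and Crh (8.18, SE 0.73), Adarb2 (4.85, SE 0.30), Erbb4 (3.54, SE 0.29) and Prox1 (2.87, SE 0.30, edgeR adjusted p = 0.00842) were also higher. Gad1 rose by 2.48 (SE 0.39, edgeR adjusted p = 0.0251), while Slc17a7 fell by 4.68 (SE 0.73, edgeR adjusted p = 0.0259). Slc1a3, a glial glutamate transporter gene, fell by 2.87 (SE 0.40) beside them. Rbfox3 (−0.12, SE 0.34, edgeR adjusted p = 0.947) and Ndnf (edgeR adjusted p = 0.0768) did not pass. Outside the lists, Slc5a7, Dach2 and Abcb5 were at least 93.3-fold, 85.3-fold and 75.7-fold higher, and Iqgap2 and Cckbr at least 1050-fold and 248-fold lower.

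Of the VIP subclass list 12 of 18 genes were higher in the biological replicates, or 14 higher and 1 lower over the list alone (camera adjusted p = 6.19e-14; adjusted p = 0.126 with an estimated correlation). The caudal ganglionic eminence list had 6 of 12 higher (1.44e-10 by camera; adjusted p = 0.277 with an estimated correlation) and the pan-GABAergic list 6 of 12 (1.72e-10; adjusted p = 0.346 with an estimated correlation), or 11 each over the list alone. Excitatory genes were lower for 11 of 19 or 15 over the list alone (1.22e-13 by camera; adjusted p = 0.126 with an estimated correlation), and oligodendrocyte genes for 8 of 12 or all 12 over the list alone (8.54e-10; adjusted p = 0.277 with an estimated correlation). Astrocyte genes were lower for 3 of 14 (camera adjusted p = 0.000749; adjusted p = 0.337 with an estimated correlation) and microglia genes for 1 of 11 (0.000126; adjusted p = 0.375 with an estimated correlation). Immediate early genes showed 0 calls of 20 (camera adjusted p = 0.914). By edgeR 479 of 16587 genes passed, 197 higher and 282 lower. Oligodendrocyte precursor genes had 0 of 8 called, or 4 lower over the list alone (camera adjusted p = 0.00277; adjusted p = 0.346 with an estimated correlation). VIP genes called here and in the technical replicates of 100 nuclei overlapped by 184 higher and 243 lower, with 0 in opposite directions.

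A virus-based sort tested whether VIP nuclei could be profiled without the transgenic tag. Vip averaged 2057 CPM (SD 815, n = 3) against 2.25 (SD 1.96, n = 3), a log2 fold change of 9.82 (SE 0.99, edgeR adjusted p = 0.000329). The bombesin-family receptor gene Grpr was at least 448-fold higher, and Mybpc1 (7.14, SE 0.68), Crh (6.48, SE 0.90), Adarb2 (5.64, SE 0.50), Gad1 (3.43, SE 0.36) and Prox1 (2.00, SE 0.42, edgeR adjusted p = 0.0191) were higher. Slc17a7 fell by 3.03 (SE 0.41, edgeR adjusted p = 0.00197) and Slc1a3 by 6.24 (SE 0.70), and Rbfox3 did not pass (0.33, SE 0.30, edgeR adjusted p = 0.709). Serpina12 (9.49, SE 0.85) and Abcb5 (8.46, SE 1.02) were higher outside the lists, and Plxnb3, Selplg and Csf3r were at least 676-fold, 289-fold and 192-fold lower. VIP subclass genes were higher for 12 of 19 (camera adjusted p = 1.16e-11, and 0.0499 with an estimated correlation), caudal ganglionic eminence genes for 8 of 12 (4.93e-12, and 0.0499) and pan-GABAergic genes for 9 of 12 (5.49e-13, and 0.0499). Excitatory genes were lower for 7 of 19 or 11 over the list alone (camera adjusted p = 2.96e-10; adjusted p = 0.145 with an estimated correlation). Oligodendrocyte genes were lower for 7 of 12 (3.12e-09 by camera; adjusted p = 0.116 with an estimated correlation), their precursors for 3 of 8 (3.85e-06, and 0.0499) and microglia genes for 5 of 11 (5.45e-06; adjusted p = 0.321 with an estimated correlation). The nonVIP libraries differed in glia, as replicate 2 held 867 CPM of the microglia list and 1988 of the astrocyte list, against 210 and 876 in replicate 1 and 213 and 944 in replicate 3. Astrocyte genes were lower for 3 of 14 (camera adjusted p = 0.000167; adjusted p = 0.335 with an estimated correlation), and of the Pvalb subclass list 4 of 10 were higher (0.00245; adjusted p = 0.253 with an estimated correlation). By edgeR 1007 of 17866 genes passed, 484 higher and 523 lower.

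Whether the VIP enrichment differed between the virus and the transgenic sort was asked with an interaction over the virus and the biological replicate libraries. The difference was 0.33 for Vip (SE 0.98, edgeR adjusted p = 1), −0.91 for Prox1 (edgeR adjusted p = 0.927), 0.92 for Gad1 (edgeR adjusted p = 0.904) and 1.63 for Slc17a7 (edgeR adjusted p = 0.828). Among 21146 genes 0 passed by edgeR, with 1260 at unadjusted p below 0.05 and 92 called by DESeq2. By transcripts the virus libraries were female and the biological replicates male, so sex went with the sort. Excitatory genes as a list were less depleted in the virus sort (20 tested, 0 called, 4 higher over the list alone, camera adjusted p = 3.81e-05; adjusted p = 0.836 with an estimated correlation). VIP genes called in both sorts overlapped by 164 higher and 126 lower, with 0 in opposite directions and r = 0.566 between log2 fold changes.

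NDNF nuclei were compared with nonNDNF nuclei to profile a rarer interneuron class. Ndnf, which encodes a secreted neurotrophic factor, averaged 589 CPM (SD 9.87, n = 3) against 0, at least 5050-fold higher (edgeR adjusted p = 6.01e-06). The matrix gene Hapln1 (9.39, SE 0.53), the extracellular glycoprotein gene Reln (5.81, SE 0.35) and the receptor kinase gene Kit (5.64, SE 0.32) were higher, Reln reaching 3684 CPM (SD 268) against 65.8 (SD 28.3). Gad2 rose by 5.03 (SE 0.36), Adarb2 by 4.95 (SE 0.30) and Gad1 by 4.62 (SE 0.58, edgeR adjusted p = 0.00093). Slc17a7 fell by 4.78 (SE 0.69, edgeR adjusted p = 0.00208), the layer genes Tshz2 by 7.19 (SE 0.58) and Rorb by 6.72 (SE 0.65), and the peptide genes Sst by 3.33 (SE 0.86) and Cck by 2.40 (SE 0.36). Vip (−3.68, SE 1.91, edgeR adjusted p = 0.408), Prox1 (3.44, SE 1.01, edgeR adjusted p = 0.0768) and Rbfox3 (−0.20, SE 0.44, edgeR adjusted p = 0.934) did not pass. Rgs5 (8.03, SE 1.14) and Vcan, also markers of vascular and precursor cells, were higher in NDNF nuclei, and the astrocyte gene Slc1a2 fell by 1.25 (SE 0.25). Outside the lists, Prom1 and Frem2 were at least 498-fold and 192-fold higher and Col6a1, Bace2 and Gcnt4 at least 225-fold, 170-fold and 154-fold lower. Has2, at least 146-fold higher, overlaps Has2os and remained uncertain.

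The NDNF and Lamp5 subclass list had 8 of 16 genes higher in NDNF nuclei, or 9 over the list alone (camera adjusted p = 3.28e-10; adjusted p = 0.0987 with an estimated correlation). Pan-GABAergic genes were higher for 7 of 12, or all 12 over the list alone (2.19e-13 by camera; adjusted p = 0.0987 with an estimated correlation), and caudal ganglionic eminence genes for 5 of 11 with 1 lower (1.11e-05; adjusted p = 0.0987 with an estimated correlation). Excitatory genes were lower for 10 of 19, or 16 over the list alone (5.06e-16 by camera; adjusted p = 0.0987 with an estimated correlation). VIP subclass genes were higher for 1 and lower for 3 of 9 (camera adjusted p = 0.13), Sst subclass genes higher for 1 and lower for 3 of 9 (0.0015; adjusted p = 0.151 with an estimated correlation). Immediate early genes were lower for 3 of 18 in NDNF nuclei, Egr1 by 2.47 (SE 0.64; camera adjusted p = 0.000294 for the list; adjusted p = 0.318 with an estimated correlation). A single comparison library stood apart there: nonNDNF replicate 1 held 598 CPM of the list, against 133 and 205 in the other nonNDNF libraries and 106 to 134 in the NDNF ones. Late response genes were higher for 1 and lower for 4 of 19 (camera adjusted p = 0.0164; adjusted p = 0.151 with an estimated correlation), and nonNDNF replicate 1 was again highest with 927 CPM of that list, against 589 and 572 in the other nonNDNF libraries and 417 to 648 in the NDNF ones. In the vascular list 1 of 5 genes was higher (camera adjusted p = 0.00155; adjusted p = 0.134 with an estimated correlation). By edgeR 1023 of 16893 genes passed, 434 higher and 589 lower.

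The NDNF enrichment was compared with the VIP enrichment of the biological replicates by an interaction. Hapln1 (11.55, SE 0.81), Reln (6.97, SE 0.49) and Gad2 (2.73, SE 0.49) were more enriched in the NDNF sort, with edgeR adjusted p of 1.93e-06, 1.93e-06 and 0.00753. Vip (−13.01, SE 2.09), Crh (−9.50, SE 1.59), Elfn1 (−9.43, SE 1.14) and Cck (−2.96, SE 0.50) were more enriched in the VIP sort, as were the chloride channel gene Cftr (−11.96, SE 1.93) and the secreted Wnt enhancer gene Rspo2 (−10.69, SE 1.18). Arhgap6, without counts in VIP nuclei, was also more enriched in the NDNF sort (edgeR adjusted p = 7.93e-06). Gad1 (2.11, SE 0.73, edgeR adjusted p = 0.258) and Prox1 (0.49, SE 1.17, edgeR adjusted p = 1) did not pass. VIP subclass genes were lower for 6 of 18, or 9 over the list alone (camera adjusted p = 2.93e-21, and 0.000759 with an estimated correlation), and NDNF and Lamp5 genes higher for 8 of 18, or 11 over the list alone (1.64e-08; adjusted p = 0.0926 with an estimated correlation). Sst subclass genes were lower for 3 of 12 (camera adjusted p = 0.00467; adjusted p = 0.119 with an estimated correlation) and 1 of 10 oligodendrocyte precursor genes was higher (6.04e-05; adjusted p = 0.119 with an estimated correlation). The Sst list holds Crh and Elfn1, named above as more enriched in the VIP sort, and Crh is also on the VIP subclass list. By edgeR 300 of 20149 genes passed, 179 higher and 121 lower. The NDNF sort was female and the biological replicates male by transcripts, so genotype, sort and sex were not separated here.

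Monkey Prox1+ nuclei were compared with Prox1- nuclei, both NeuN+ by their titles, to extend the approach to an animal without a transgenic tag. The replicates of each group were technical, so p and SD in the monkey sorts measured the spread between libraries and not between animals. PROX1 averaged 163 CPM (SD 14.4, n = 2) and VIP 268 (SD 22, n = 2) in Prox1+ nuclei against 0 in Prox1- nuclei, at least 589-fold and at least 967-fold higher (edgeR adjusted p = 5.97e-07 and 0.00041). The receptor kinase gene KIT (10.60, SE 0.51), the calcium-binding protein gene CALB2 (8.35, SE 0.62), the chemokine gene CXCL14 (8.06, SE 0.50) and the transcription factor gene NR2F2 (6.69, SE 0.67) were higher. TAC3, CHRNA2 and SALL1 were at least 1020-fold, 333-fold and 197-fold higher, and NDNF at least 48.3-fold. CRH (4.24, SE 0.37), RELN (3.35, SE 0.30), ERBB4 (3.32, SE 0.25), GAD2 (2.24, SE 0.31) and GAD1 (1.13, SE 0.17, edgeR adjusted p = 0.00103) were also higher. CUX2 fell by 7.40 (SE 0.64) and SV2B by 6.86 (SE 0.52), as did RORB. SST fell by 3.07 (SE 0.52), the immediate early gene EGR1 by 5.30 (SE 0.89) and RBFOX3 by 1.2 (SE 0.16), and PLA2G4A and FAP were at least 174-fold and 94.2-fold lower. VIP subclass genes were higher for 6 of 13, or 9 over the list alone (camera adjusted p = 1.96e-05; adjusted p = 0.117 with an estimated correlation), and caudal ganglionic eminence genes for 7 of 11 and pan-GABAergic genes for 6 of 10 (7.36e-07 each; adjusted p = 0.106 with an estimated correlation). Excitatory genes were lower for 13 of 14 (camera adjusted p = 9.86e-14; adjusted p = 0.0621 with an estimated correlation), and by edgeR 2079 of 16820 genes passed, 860 higher and 1219 lower.

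Against unselected Dapi nuclei, monkey Prox1+ nuclei lost glial transcripts as well. The Prox1+ and Prox1- groups were both NeuN+ by their titles, so differences from Dapi nuclei do not separate Prox1 from NeuN. The myelin gene MOBP fell by 7.48 (SE 0.32) and the astrocyte transporter gene SLC1A2 by 3.86 (SE 0.17). VIP rose by 5.34 (SE 0.92), PROX1 by 1.79 (SE 0.24) and GAD1 by 1.38 (SE 0.17), while RBFOX3 did not pass (−0.17, SE 0.16, edgeR adjusted p = 0.56). SCGN was at least 66.3-fold higher and HTR2C rose by 8.37 (SE 0.96), whereas SHROOM4 and GPR37 were at least 1400-fold and 522-fold lower. All 11 oligodendrocyte genes were lower (camera adjusted p = 1.44e-11; adjusted p = 0.0653 with an estimated correlation), as were 8 of 12 astrocyte genes with 1 higher (0.000445; adjusted p = 0.262 with an estimated correlation). In Prox1- against Dapi nuclei PROX1 was at least 171-fold lower and RBFOX3 rose by 1.03 (SE 0.16). Pan-neuronal genes were higher there for 5 of 11 (camera adjusted p = 0.000576; adjusted p = 0.236 with an estimated correlation) and all 11 oligodendrocyte genes lower (5.23e-15; adjusted p = 0.0566 with an estimated correlation). By edgeR 2727 genes passed for Prox1+ and 1694 for Prox1- against Dapi.

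In mouse, Prox1+ NeuN+ nuclei were compared with Dapi nuclei as the counterpart of the monkey sort, again with technical replicates and no measure of the spread between animals. Prox1 averaged 369 CPM (SD 0.147, n = 2) against 7.58 (SD 8.63, n = 2), a log2 fold change of 5.63 (SE 0.77, edgeR adjusted p = 0.00262). Vip rose by 4.16 (SE 0.73, edgeR adjusted p = 0.00895), to 220 CPM (SD 145) from 12.4 (SD 11.8), Adarb2 by 3.32 (SE 0.21), Synpr by 3.11 (SE 0.22) and Rbfox3 by 1.46 (SE 0.27), and Htr3a was at least 126-fold higher. Neither Gad1 (0.38, SE 0.31, edgeR adjusted p = 0.574) nor Slc17a7 (0.37, SE 0.35, edgeR adjusted p = 0.636) differed. The layer genes Tshz2 (−9.25, SE 0.44), Rorb (−7.97, SE 0.48), Cux2 (−5.23, SE 0.50) and Neurod6 (−4.99, SE 0.44) were lower, as was the synaptic scaffold gene Homer1 (−2.55, SE 0.24). Slc4a4, a bicarbonate transporter gene on the astrocyte list, rose by 3.27 (SE 0.26), to 1056 CPM (SD 57.9) from 110 (SD 34.1), while Pdgfra was at least 53.1-fold lower. Tdo2, Mfsd13b and Plcg2 were at least 142-fold, 131-fold and 123-fold higher, and Col6a1 and Adamts2 at least 242-fold and 186-fold lower. Caudal ganglionic eminence genes were higher for 4 of 11 (camera adjusted p = 0.00321; adjusted p = 0.462 with an estimated correlation), and VIP subclass genes higher for 6 and lower for 2 of 13 (0.0575 by camera). On the excitatory list 11 genes were lower and 1 was higher of 20 (camera adjusted p = 3.08e-06; adjusted p = 0.462 with an estimated correlation), and precursor genes lower for 5 of 7 (0.000114; adjusted p = 0.462 with an estimated correlation). Oligodendrocyte genes were lower for 5 and higher for 1 of 12 (camera adjusted p = 0.00171; adjusted p = 0.462 with an estimated correlation) and late response genes lower for 3 of 20 (0.048; adjusted p = 0.462 with an estimated correlation). By edgeR 1390 of 17066 genes passed, 682 higher and 708 lower. On lists written after the value of Slc17a7 was seen, 12 of 14 dentate granule markers such as Glis3 (3.81) and C1ql2 (3.98) were higher and 7 of 8 cortical layer markers lower. The camera call of the dentate list was lost with an estimated correlation (0.0739).

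**Figure D4:**
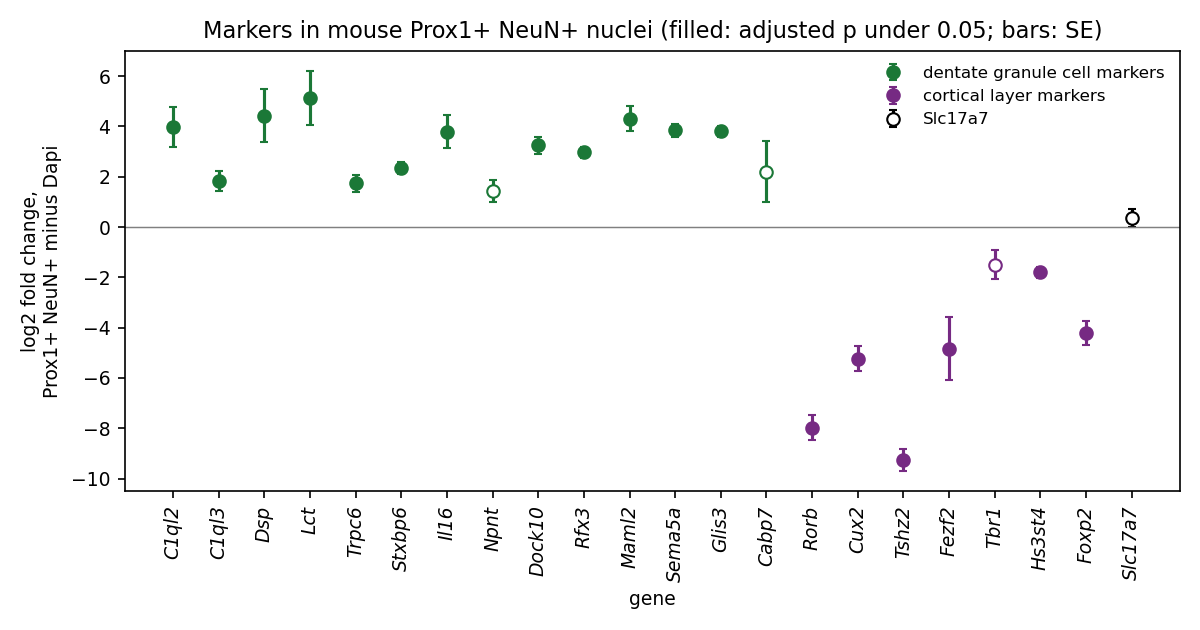
Dentate granule and cortical layer markers in mouse Prox1+ NeuN+ against Dapi nuclei, lists chosen after the values of Slc17a7 were seen. Points are log2 fold changes per gene with bars of 1 SE over 2 technical replicates per group, filled at an adjusted p below 0.05, and not every listed marker is drawn; Slc17a7 differed by 0.37 while Rorb fell by 7.97 and Glis3 rose by 3.81.

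The Prox1+ enrichments of mouse and monkey were then compared over genes with the same symbol. Across 9104 genes tested in both species the log2 fold changes correlated at r = 0.158 (rho = 0.042). Rorb (−7.97 in mouse, −5.98 in monkey) and Sv2b (−6.39, −5.83) were lower and Gpc3 (6.17, 7.64) higher in both, whereas Mctp2 was lower in mouse (−6.95) and higher in monkey (6.73); these genes were chosen after their values were seen. In total 67 genes were higher in both species against 28.1 for independent lists, 169 were lower in both against 53, and 153 were called in opposite directions against 82.6. The opposite calls included dentate granule markers higher in the mouse sort and chosen after their values were seen, Maml2 (4.3 in mouse, −4.25 in monkey), Dock10 (3.24, −1.49) and Stxbp6 (2.34, −4.26). Calls in both species came from technical replicates, so these counts do not measure replication between animals.

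The time course began with VIP and nonVIP nuclei at time 0. Vip averaged 3269 CPM (SD 796, n = 3) against 5.49 (SD 9.5, n = 3), a log2 fold change of 9.10 (SE 1.44, edgeR adjusted p = 0.000145). Grpr was at least 291-fold higher in VIP nuclei, and Tac2 (6.72, SE 0.91), Adarb2 (4.13, SE 0.47), the prohormone convertase gene Pcsk1 (3.21, SE 0.55), Gad1 (2.92, SE 0.39) and Prox1 (2.77, SE 0.54) were higher. Fos was also called higher (5.31, SE 1.16), but VIP replicate 3 held 48.7 CPM of it and the other VIP libraries 5.84 and 11.4. The growth factor gene Bdnf fell by 6.85 (SE 1.06), to 0.129 CPM (SD 0.223) from 22.7 (SD 7.64), Nrgn by 5.15 (SE 0.58) and Slc17a7 by 3.23 (SE 0.90, edgeR adjusted p = 0.0262), and the microglial gene Siglech was at least 709-fold lower. Rbfox3 (−1.10, SE 0.37, edgeR adjusted p = 0.0704) and Ndnf (edgeR adjusted p = 0.151) did not pass. VIP subclass genes were higher for 12 of 20 (camera adjusted p = 2.64e-13, and 1.36e-05 with an estimated correlation), and oligodendrocyte genes lower for 11 of 12 (3.07e-18, and 1.36e-05). The nonVIP libraries of time 0 were rich in glia, with 5473 to 10190 CPM of the oligodendrocyte list and 831 to 1939 of the microglia list, against 1616 to 4970 and 124 to 1141 in nonVIP libraries of the later times. By edgeR 1251 of 18046 genes passed, 590 higher and 661 lower.

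Immediate early genes led the response of VIP nuclei over time. At time 0.5 Nr4a3 averaged 253 CPM (SD 81, n = 3) against 5.99 (SD 2.59, n = 3) at time 0, a log2 fold change of 5.42 (SE 0.69, edgeR adjusted p = 0.000329). Fosl2 rose by 5.52 (SE 0.80, edgeR adjusted p = 0.0017) and Nr4a1 by 2.94 (SE 0.44, edgeR adjusted p = 0.00198), and these 3 genes were the only ones called, with 1134 at unadjusted p below 0.05 and 64 by DESeq2. Fosb (at least 97.3-fold), Bdnf (5.19, SE 1.05) and Homer1 (1.97, SE 0.43) did not pass (edgeR adjusted p = 0.108, 0.108 and 0.193), and neither did Vip (−0.01). The immediate early list had 3 of 23 genes higher, or 18 over the list alone (camera adjusted p = 3.97e-37, and 9.66e-06 with an estimated correlation), and the late response list 0 of 20, or 3 over the list alone (0.00481, and 0.0197). At time 1 Fosl2 (5.32, SE 0.79), Nr4a3 (3.35, SE 0.64) and Nr4a1 (2.44, SE 0.43) were still higher by edgeR (adjusted p = 0.0057, 0.0489 and 0.0458), and Xist fell by 12.86. The immediate early list had 3 genes higher at time 1, or 15 over the list alone (camera adjusted p = 7.73e-26, and 9.71e-05 with an estimated correlation). At time 3 the long non-coding RNA Mir670hg rose by 2.26 (edgeR adjusted p = 0.0169) and the phosphodiesterase gene Pde7b fell by 2.69 (edgeR adjusted p = 0.0108). In VIP nuclei too, sex went with time at times 1 and 3, and with sex by transcripts as a covariate 0 genes stayed called at either time. At time 3 of the fit without it, 0 immediate early genes passed in VIP nuclei, or 5 higher and 1 lower over the list alone (camera adjusted p = 0.00283; adjusted p = 0.555 with an estimated correlation).

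In nonVIP nuclei the genes called included late response genes, a list that also passed in VIP nuclei at time 0.5. At time 0.5 Fosl2 (7.46, SE 0.96), Nr4a3 (5.22, SE 0.69) and Nr4a1 (2.81, SE 0.44) rose with edgeR adjusted p of 0.000177, 0.000177 and 0.00123. Homer1 reached 1313 CPM (SD 228, n = 3) from 118 (SD 66.7, n = 3), a rise of 3.48 (SE 0.46), and Pcsk1 rose by 4.24 (SE 0.57). Gadd45b, a DNA damage response gene, was at least 76.5-fold higher, and Cacng5, Gng4 and Angptl1 at least 49.1-fold, 48.9-fold and 48.8-fold. All 49 genes called at time 0.5 were higher, while 1782 had unadjusted p below 0.05. At time 1 Fosl2 (7.08, SE 0.95), Nr4a3 (5.09, SE 0.69), Pcsk1 (4.2, SE 0.57) and Homer1 (3.12, SE 0.45) remained higher and Gadd45b was at least 92.2-fold higher, with 96 genes higher and 5 lower. At time 3 Gadd45b was at least 36.3-fold higher, Lamb1 fell by 5.57 and Pde1c by 3.15, with 25 genes higher and 13 lower, and Fosl2 (4.18, SE 0.95, edgeR adjusted p = 0.0646) no longer passed. Xist fell by 11.70 and 10.17 at times 1 and 3, so at these times sex went with time. With sex by transcripts as a covariate, chosen after seeing the data, 32 nonVIP genes were called at time 0.5, 31 of them among the 49, 12 stayed called at time 1, Fosl2 (6.78) and Nr4a3 (5.24) among them, and 0 at time 3. Leaving out each library in turn gave 27 to 118 nonVIP calls at time 0.5, 52 to 151 at time 1 and 4 to 105 at time 3.

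Immediate early genes as a list were higher in nonVIP nuclei for 14, 13 and 1 of 23 at times 0.5, 1 and 3, or 20, 20 and 8 over the list alone (camera adjusted p = 1.08e-32, 2.2e-29 and 4.15e-05; 2.22e-05, 3.24e-05 and adjusted p = 0.069 with an estimated correlation). Late response genes were higher for 2, 3 and 0 of 20, or 5 and 6 over the list alone at the earlier times (camera adjusted p = 1.84e-07, 5.22e-10 and 0.00251; 0.00023, 3.24e-05 and 0.0202 with an estimated correlation). The microglia and oligodendrocyte lists were lower in nonVIP nuclei at time 0.5 as lists with 0 genes called (camera adjusted p = 3.13e-09 and 1.75e-05; 0.0457 and 0.00988 with an estimated correlation), so the glial share of nonVIP libraries moved beside the response. Of 49 and 96 genes higher in nonVIP nuclei at times 0.5 and 1, 43 were shared, against 0.26 for independent lists. The log2 fold changes of nonVIP nuclei at these times correlated at r = 0.742 with a covariance of 2.643, against 0.486 and 0.947 in 20 simulations of unchanged groups, and part of the excess of shared calls may come from the shared time 0 libraries, which were too few to divide. Fosl2, Nr4a1 and Nr4a3 were called higher in both VIP and nonVIP nuclei at times 0.5 and 1. Of the 49 nonVIP genes at time 0.5, 44 had the same sign in VIP nuclei, as had 77 of 101 at time 1 and 22 of 38 at time 3. Vip, Gad1, Slc17a7 and Prox1 were not called at any time in VIP or nonVIP nuclei.

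Interactions asked whether VIP and nonVIP nuclei responded differently. At time 0.5 Gm33206 (−8.20, SE 1.25) and Cacng5 passed by edgeR (adjusted p = 0.00875 and 0.0152), both called as rising in nonVIP nuclei alone, from near 0 for Gm33206 and from 0 for Cacng5. Cpeb3, which encodes a regulator of translation, differed by −2.23 at time 1 (SE 0.39, edgeR adjusted p = 0.0277): it went from 325 CPM (SD 100) to 210 (SD 74.7) in VIP and from 245 (SD 23.5) to 743 (SD 155) in nonVIP nuclei. Predicted genes Gm47088 (−7.83, SE 1.40), Gm33206 (−7.09, SE 1.23) and Gm43519, the last at 0 in nonVIP nuclei at time 0, also passed at time 1, and Gm43519 and Gm33206 (−8.41, SE 1.25) at time 3. Apart from Cpeb3, the genes that passed at any time averaged at most 0.162 CPM in nonVIP nuclei at time 0. A lower yield of those libraries remains open for these genes. Single genes of these interactions depended on single libraries, as leaving one out gave from 0 to 18 calls at time 0.5 and from 0 to 25 at time 1. The larger rises of Homer1 (difference −1.52, SE 0.60) and Pcsk1 (−2.64, SE 0.72) in nonVIP nuclei at time 0.5 did not pass (edgeR adjusted p = 0.578 and 0.498). Immediate early genes did not differ as a list at times 0.5, 1 or 3 (camera adjusted p = 0.332, 0.0848 and 0.572), with 4, 5 and 1 lower over the list alone. Late response genes differed at time 1 only (camera adjusted p = 0.0207; adjusted p = 0.13 with an estimated correlation). Oligodendrocyte genes fell more in nonVIP nuclei as a list at times 0.5, 1 and 3 (camera adjusted p = 0.00103, 0.0106 and 9.9e-05; adjusted p = 0.11, 0.156 and 0.0336 with an estimated correlation), as did microglia genes (0.000127, 0.00764 and 0.000134 by camera; adjusted p = 0.321, 0.437 and 0.502 with an estimated correlation).

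**Figure D5:**
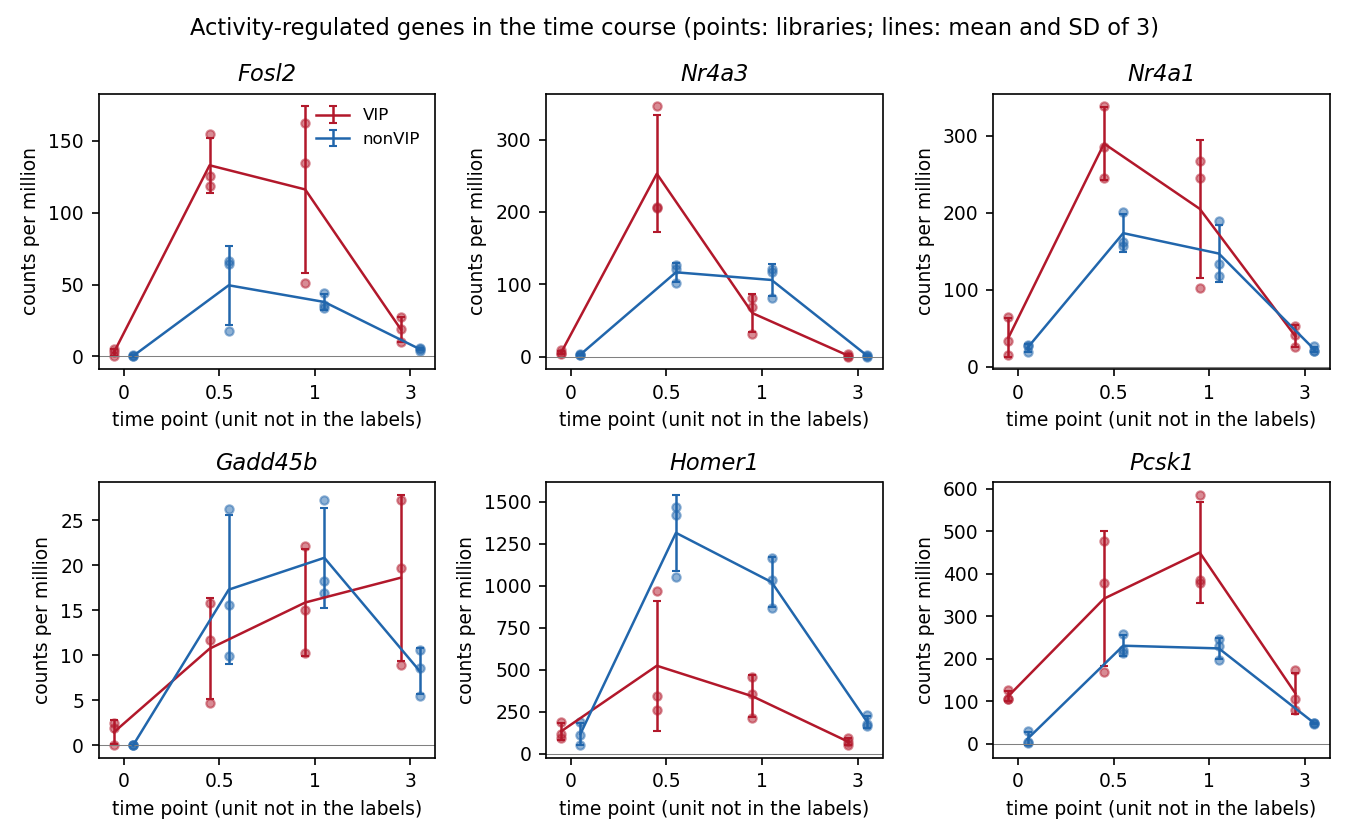
Activity-regulated genes in the time course. Points are libraries and lines group means with bars of 1 SD in CPM, for VIP and nonVIP nuclei at times 0, 0.5, 1 and 3 with the unit not in the labels; Nr4a3 in VIP nuclei went from 5.99 to 253 CPM at time 0.5.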

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

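Tests of other splits of the libraries named here were planned, and the comparison of the per-sample count files with the series table was chosen after its result was seen.

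The difference between the NDNF and the VIP enrichment was singled out because the interaction itself passed: 300 genes were called by edgeR. It rests on 3 libraries per NDNF group and 2 per VIP group from separate sorts, and by transcripts the NDNF and nonNDNF libraries were female and the VIP and nonVIP ones male, so genotype, sort and sex were not separated.

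The responses of VIP and nonVIP nuclei differed for single genes, which were singled out because their interaction passed. At time 0.5 these were 2 genes, Gm33206 (−8.20) and Cacng5 (−7.90). At time 1 they were 4: Gm43519 (−9.35), Gm47088 (−7.83), Gm33206 (−7.09) and Cpeb3 (−2.23). At time 3 they were 2, Gm43519 (−8.86) and Gm33206 (−8.41). Apart from Cpeb3, these genes were near 0 in nonVIP nuclei at time 0, and a lower yield of those libraries remains open for them. Libraries were exchanged between times in splits that numbered 30 with the real one. With the real split counted, 4 called at least 2 genes at time 0.5, 4 called at least 4 at time 1 and 2 called at least 2 at time 3. The highest counts among the exchanged splits were 13, 27 and 2. Chance was therefore not excluded for any of these counts. The splits with 13 and 27 calls gave several times the real values of 2 and 4. Splits that exchanged every library of a single population were allowed, and these keep its response to time. The high counts therefore do not separate that response from a structure of the samples, which was not tested. Where nonVIP nuclei had no counts at time 0, as for Cacng5 and Gm43519, the printed differences are fitted values without a measured size.

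The count files of replicate 1 at time 0.5 were singled out because they disagree with the series table. Vip was at 0.176 CPM in the file of the VIP library and at 1280 CPM in that of the nonVIP library, and in the series table the assignment was the opposite. Other markers in the series table went with its titles: replicate 1 of VIP held 607 CPM of Gad1, 704 of the excitatory list and 214 of the oligodendrocyte list, and replicate 1 of nonVIP 87.8, 3190 and 1928. These levels argue against the names of the per-sample files.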

How the results depend on the processing

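Tests chosen after the results were seen were those without genes on chromosomes X and Y, with sex as a covariate, from the per-sample count files, of detection without the 50 nuclei libraries and of the species comparison without each library.

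No alternative gave a gene called in the opposite direction. By DESeq2 1546 of 1699 values of named genes had the same status, called or not called, while 12 lost a call and 141 gained one. Leaving out a library left the status the same for 10856 of 11407, with 447 calls lost and 104 gained. Genes called in neither fit count as the same here, so these shares do not measure how many calls were kept.

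Counts of calls by DESeq2 were larger: 1385 genes for the biological replicates, 1797 for the virus sort, 92 for virus minus transgenic, 1708 for NDNF, 654 for NDNF minus VIP, 2221 for mouse Prox1+ and 2120 at time 0. In the time course they were 64 for VIP and 282 for nonVIP at time 0.5, 150 and 335 at time 1 and 92 and 252 at time 3, with 38, 107 and 130 for the interactions. DESeq2 also called more unchanged genes in the simulated data. The cause was not tested.

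Without the low-count filter the counts were 1301 for the biological replicates, 1833 for the virus sort, 166 for virus minus transgenic, 1671 for NDNF, 697 for NDNF minus VIP and 2173 for mouse Prox1+. They were 72 for VIP and 232 for nonVIP at time 0.5, 111 and 253 at time 1 and 67 and 254 at time 3, with 86, 126 and 159 for the interactions. The cause was not tested.

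Replicate numbers were checked for pairing. Libraries of the same number did not deviate together in every pair of any comparison, with correlations of 0.071 to 0.166 in the virus sort, 0.066 to 0.286 in the NDNF sort and 0.011 to 0.119 for VIP and nonVIP at time 0.5 against the minimum of 0.1. Libraries were each other's closest match by number for 3 of 3 pairs in the virus sort and for VIP and nonVIP at time 3. This held for 2 of 3 at times 0, 0.5 and 1 and for 1 of 3 in the NDNF sort. Pairing by animal was therefore not excluded, and the main fits did not use it. With a replicate block the counts were 1842 at 200 nuclei, 1863 at 500, 829 for the biological replicates, 484 for NDNF minus VIP and 2130 for mouse Prox1+. In the time course the replicate block gave 1 for the time 0.5 interaction, a gene other than the 2 called without it, 10 for VIP at time 1, 0 for the time 1 interaction, where Cpeb3 had an edgeR adjusted p of 0.139, and 7 for VIP at time 3. The block moved the median of all genes by −0.131 at 500 nuclei and −0.11 in the time 1 interaction.

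Relative log expression scaling left 1 call for VIP at time 1. With the technical replicates summed as an additional replicate the biological comparison called 1280 genes. A fit of the time 0 libraries alone called 332, and fits of nonVIP libraries alone called 67 at time 1 and 21 at time 3. The cause was not tested.

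Without genes on chromosomes X and Y, VIP nuclei had 2 calls at time 1 and 2 at time 3. With sex by transcripts as a covariate, nonVIP nuclei had 32 calls at time 0.5, 12 at time 1 and 0 at time 3, and VIP nuclei 0 at times 1 and 3. Fosl2 in nonVIP nuclei at time 1 was kept (6.78, edgeR adjusted p = 0.0245). The covariate reversed Eif2s3y (−0.75) and Tsix (0.36) at time 1 and Xist (1.37), Eif2s3y (−0.31) and Tsix (1.44) at time 3 in nonVIP nuclei. The covariate rests on the libraries of time 0.5, where sexes were mixed, since all libraries of each other time had 1 sex.

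With the per-sample files, 712 genes were called at time 0, 1 for VIP, 60 for nonVIP and 1 for the interaction at time 1, and 0 for VIP and 6 for nonVIP at time 3. These files reversed 4 list directions at time 0.5: the VIP subclass list in VIP nuclei (limma camera adjusted p = 0.00348), the excitatory list in nonVIP nuclei (0.619), and in the interaction the caudal ganglionic eminence list (7.22e-05) and the excitatory list (0.00371).

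Leaving out each library in turn gave 890 to 994 calls at 50 nuclei, 1784 to 2796 at 100, 1144 to 3624 at 200, 876 to 3217 at 500 and 718 to 1660 at 800. It gave 449 to 1213 in the virus sort, 0 to 4 for virus minus transgenic, 580 to 1145 for NDNF and 919 to 1554 for mouse Prox1+. In monkey the ranges were 1170 to 1419 for Prox1+ against Prox1-, 1746 to 2269 for Prox1+ against Dapi and 801 to 1409 for Prox1- against Dapi. In the time course they were 781 to 1227 at time 0, 3 to 13 for VIP and 27 to 118 for nonVIP at time 0.5, 1 to 15 and 52 to 151 at time 1, and 0 to 22 and 4 to 105 at time 3. The interactions had 0 to 18, 0 to 25 and 1 to 29. The cause was not tested.

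The correlation between mouse and monkey ranged from 0.103 to 0.184 without each library, and was 0.195 over genes called in either species. Without the 50 nuclei libraries the relation of nonVIP detection to the number of nuclei reversed to r = −0.69 (permutation p = 0.0115), while without the 800 nuclei libraries it was r = 0.652 (permutation p = 0.0227). On log2 of CPM plus 5, replicates of VIP nuclei correlated at 0.939, 0.941, 0.922, 0.905 and 0.923 from 50 to 800 nuclei and those of nonVIP nuclei at 0.929, 0.954, 0.962, 0.963 and 0.944. At equal library totals the VIP values were 0.885, 0.885, 0.859, 0.845 and 0.869, and the nonVIP values 0.864 at 50, 0.925 at 200, 0.913 at 500 and 0.9 at 800 nuclei.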

Other observations

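Tests chosen after the results were seen were those of cell-type regulation of sex-linked genes, of the count of 24 libraries, of cortical excitatory nuclei, of glial share and the further test of dropout, and the channel and receptor families were grouped after their genes were seen.

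Metabotropic glutamate receptor genes were lower in NDNF than in nonNDNF nuclei for 5 of 7 tested (camera adjusted p = 8.51e-05; adjusted p = 0.51 with an estimated correlation), with Grm2 down by 6.11, Grm3 by 3.84 and Grm7 by 3.08. Of 18 ionotropic glutamate receptor genes 3 were higher, Grik1 (4.57), Grin3a (3.14) and Grik2 (2.47), and 1 lower, Gria3 (−1.07), without a shift of the family (camera adjusted p = 0.812). Of 71 potassium channel genes 4 were higher, among them Kcnip1 (3.19), and 11 lower, among them Kcnh4 (−7.93), and the family did not pass (camera adjusted p = 0.106).

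The sex-linked pattern of the nuclei series was set against 2 explanations. If nonVIP nuclei of 100 to 800 came from females and VIP nuclei from males, X-linked genes expressed from both copies would be lower in VIP nuclei. Their median log2 fold change was −0.01, against 0.02 at 50 nuclei, and this test decided nothing because its members went both ways. All 24 libraries had Y-linked genes or Xist on the side of their population, which restates the pattern. Regulation by cell type predicted sex-linked calls between VIP and nonVIP nuclei of 1 sex, and 0 of 4 such comparisons had one, so the tables argue against it and different animals for the populations remain the possible explanation.

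The unchanged Slc17a7 in mouse Prox1+ nuclei was set against 2 sources of excitatory nuclei. If dentate granule nuclei were in the sort, their markers would be higher, and 12 of 14 were, with Maml2 at 2160 CPM (SD 53.3, n = 2 technical replicates), Rfx3 at 1930 (SD 208) and Glis3 at 1350 (SD 109). Cortical excitatory nuclei passing the gate would raise layer markers with Slc17a7, but the median of these lay below it by 5.4 (difference −5.4), which argues against them. The camera call of the dentate list was lost with an estimated correlation (0.0739). In VIP nuclei, where Prox1 is also enriched, the markers had 0 higher and 7 lower of 13 in the virus sort, 0 and 2 of 12 in the biological replicates and 2 and 4 of 10 at 100 nuclei, and in NDNF nuclei 2 and 2 of 13. The values are consistent with granule nuclei in the tissue taken, as a hypothesis, although the labels name visual cortex and Prox1+ nuclei of other classes were not tested.

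Another pattern was 13 genes, near 0 in nonVIP nuclei at time 0 except for Kcnc2 at 108 CPM (SD 32.4), that were higher at each later time, with fitted medians of 8.12, 7.24 and 6.73. A larger glial share at time 0 would lower neuronal genes by as much, yet the pan-neuronal list differed by a median of 0.37. For independent dropout, 2 genes (Fap and Gadd45b) were at 0 in all 3 libraries and at 5 CPM or more in the 9 later ones, against 0.17 for independence, a ratio of 11.8 that exceeded the written bound of 3 but covered 4 of the 13 genes and rests on 2. A further test, chosen after that value, found 83 genes against 24.1 (ratio 3.45), but the ratio was higher at the other times (12.9, 6.61 and 14.8), so it decided nothing. At equal totals nonVIP libraries at time 0 had 15363 genes (SD 647, n = 3) against 17552, 17294 and 17133 later, and a lower yield of these libraries and a response remain open.

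Fewer genes detected in VIP libraries of more nuclei was at first taken as a pattern to weigh and was dropped after its values were seen. The measured values were r = −0.887 with the number of nuclei, −0.86 without the 50 most abundant genes, 0.907 for the share of counts in these genes and −0.92 for the share in excitatory and glial lists.

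Other splits of the same 6 libraries numbered 10 with the real one in each comparison of 3 against 3, and 1 of the 10, the real split, gave as many calls in every comparison, so the splits are too few for a share under 0.05. Real values and the highest other were 1437 and 0 at 50 nuclei, 2764 and 0 at 100, 2916 and 0 at 200, 2816 and 0 at 500, 1767 and 0 at 800, 1007 and 0 for the virus sort and 1023 and 0 for NDNF. In the time course they were 1251 and 14 at time 0, 3 and 2 for VIP and 49 and 1 for nonVIP at time 0.5, 6 and 5 and 101 and 2 at time 1, and 4 and 1 and 38 and 4 at time 3.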
